A study of Mus musculus with 20 samples.

How the data were processed

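The series holds 20 RNA-seq libraries of CD4+ T cells from SJL mice, 5 from each of the genotypes XX, XY, XXSry and XYSry. Per the labels, the donors were gonadectomized at 4 to 6 weeks of age and the cells came from axillary, brachial and inguinal lymph nodes. The labels describe the culture in 2 ways. The series text has mice immunized with a proteolipid protein peptide in complete Freund's adjuvant, nodes taken after 10 days, and restimulation with the peptide for 36 h before CD4+ cells were sorted, and it speaks there of female mice only. The sample protocol has CD4+ cells isolated by negative magnetic selection and stimulated with beads carrying antibodies to CD3 and CD28 for 36 h. Both are given here without a choice, and whether gonadal males were immunized is not stated. The labels do not say that the libraries of a group came from separate animals, so each p measures only the spread between these libraries.

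The deposited table holds 1 raw count per Ensembl gene and library, made by the authors before deposit. The submitters' processing notes name bcl2fastq 2.17 and the genome build mm10. The aligner, the counting program, the strand setting and the annotation release are not given in the sources used here. Of 39017 genes in the table, 37693 were found in GENCODE vM21 (GRCm38, the same build as mm10) and 1324 were not, the latter holding 0.598% of the reads. Among 40 pairs of libraries compared within groups, the lowest chi-square per degree of freedom was 3.66, so no library repeats another. All 20 libraries were used and no column was left out.

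The 5 contrasts, the tests, the gene lists and the first set of alternatives were fixed before the data were examined. Counts were analysed with edgeR 4.0.16 in R 4.3.3: filterByExpr on group, which kept 15686 genes holding 99.9% of reads, TMM size factors, robust quasi-likelihood fits and quasi-likelihood F tests, with 1 coefficient per group over all 20 libraries. The contrasts were XX minus XY, XXSry minus XYSry, the mean of these (complement), gonadal females minus gonadal males averaged over complements (gonad), and the difference of the first 2 (interaction). P values were adjusted by Benjamini-Hochberg over all tested genes, and genes with an adjusted p below 0.05 are called changed. CPM values use TMM-scaled library sizes, and log2 differences are the fitted ones, with SE and 95% CI. DESeq2 1.42.0 served as the other tool.

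The 34 gene lists were X inactivation escape, Y-linked, distal X segment, X-linked immune, Th1, Th2, Th17, Treg, Tfh, T cell receptor activation, inhibitory receptors, naive and memory, cytokines and chemokines, interferon response, cell cycle, glycolysis, cholesterol synthesis, nuclear oxidative phosphorylation, mitochondrially encoded, ribosomal proteins, histone demethylase and polycomb, glucocorticoid and steroid, heat shock and stress, apoptosis and p53, T cell identity, and markers of B cells, plasma cells, CD8 T cells, NK cells, macrophages, dendritic cells, neutrophils, erythroid cells and stroma. The 32 lists with at least 5 tested members were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, adjusted over the lists of a contrast. The same test with a correlation estimated per list, and fry, stand beside it. Fry asks another question, whether the members of a list changed at all, without setting them against other genes. Members were also counted after adjustment over the list alone. All X-linked genes except Xist were tested as a set in the same way, and the chromosomes of called genes by Fisher's exact test, two-sided.

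Genes are named by a rule fixed beforehand: the check genes of the Y-linked and escape lists and Sry, the 10 called genes with the smallest adjusted p in each direction that have a symbol other than a clone or predicted-gene name and are not antigen receptor segments, and up to 4 called members of each list, or 2 where none was called. From these about 20 to 30 were printed per main contrast. Genes outside the rule are said to have been named after their values were seen.

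The alternatives fixed beforehand were RLE size factors, DESeq2, no low-count filter, a filter of at least 1 CPM in at least 5 libraries, fits of only the 2 groups compared, the replicate number as a block, each library left out in turn, and X-linked sets without the escape and distal X lists. Added after the data were seen were the mean of the B cell markers as a covariate, the 13 libraries with that mean below 3 log2 CPM, fits without the library of each group richest in mitochondrial transcripts, sets without genes within 50 kb of Xist, and the gonad contrasts within each complement. Alternatives for normalized values were not run, as the table holds counts.

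The tests were tried on simulated counts of the same depth and spread with 200 genes changed. A further 30 genes were raised by log2 0.4 as a list, and the calls include them. All were drawn among genes with a mean above 1 CPM, so the recovery does not cover weaker genes. For XX minus XY, edgeR recovered 52.2% at 1.5-fold, 85.1% at 2-fold and 93.9% at 3-fold, with 9 false among 174 calls. For the gonad contrast it recovered 86.6%, 98.5% and 98.5%, with 13 false among 221 calls, and for the interaction 34.3%, 61.2% and 90.9%, with 5 false among 131 calls. DESeq2 had 30 false among 209, 21 among 235 and 15 among 159 calls, above the nominal share. Of 200 lists drawn without a change, camera called 0%, 0.5% and 1.5%. Counts were simulated for each gene on its own, so these lists held no correlation between genes. The estimated correlation of the real lists ran from −0.033 (glucocorticoid and steroid) to 0.976 (mitochondrially encoded). The simulation therefore cannot judge camera with the preset correlation, nor false calls under variation shared between genes. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.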

Results

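RNA profiles were compared between CD4+ T cells of SJL mice of a core-genotypes model, a cross in which the sex chromosomes and the gonads are inherited apart. In these animals the testis-determining gene Sry is missing from the Y chromosome and is carried, where present, by a transgene, so that XX and XY animals without the transgene have ovaries and XXSry and XYSry animals have testes. The 20 libraries fell into 4 groups of 5, named XX, XY, XXSry and XYSry, and all donors had been gonadectomized at 4 to 6 weeks of age, per the labels. Each library held 17310943 to 21823921 gene counts. The comparisons asked which transcripts follow the sex chromosome complement, which follow the gonad type together with the Sry transgene, and whether the complement effect depends on the gonad type.

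The transcripts that identify the genotypes separated the 20 libraries without exception. Xist, the RNA that silences an X chromosome in XX cells (ENSMUSG00000086503, mm10 chromosome X, 103460366 to 103483254), reached 875 ± 200 CPM in XX and 1214 ± 167 CPM in XXSry, against 2.67 ± 0.556 CPM in XY and 3.22 ± 1.9 CPM in XYSry (SD, n = 5 each). Its counts ran from 15255 to 30177 in libraries with XX chromosomes and from 34 to 137 in those with XY chromosomes. Sry (ENSMUSG00000069036, chromosome Y, 2662471 to 2663658 in the annotation) stood at 80.4 ± 27.1 CPM in gonadal males and 0.0399 ± 0.0406 CPM in gonadal females (SD, n = 10 each), which held at most 2 Sry counts per library. The Y-linked genes Kdm5d, Eif2s3y, Ddx3y and Uty summed to 12516, 16770, 20344 and 5897 counts over the 10 libraries with a Y chromosome, and to 18, 28, 28 and 11 counts over the 10 without.

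**Figure D1:**
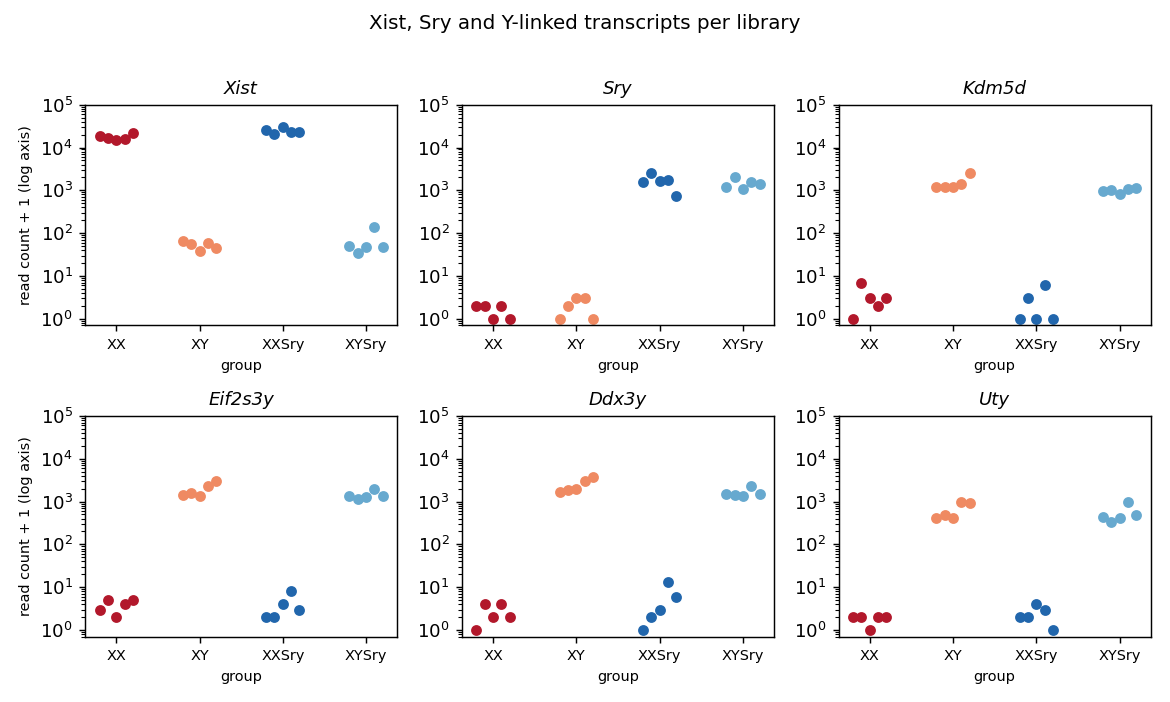
Read count plus 1 on a log axis for Xist, Sry, Kdm5d, Eif2s3y, Ddx3y and Uty, with 1 point per library in the groups XX, XY, XXSry and XYSry. Xist has at least 15255 counts in each XX and XXSry library and at most 137 in the others, Sry has at least 743 counts in each XXSry and XYSry library and at most 2 in the others, and the Y-linked genes are seen above 12 counts only in XY and XYSry.

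Between gonadal females, the complement changed few transcripts, all of them on the sex chromosomes. Kdm5c and Kdm6a, histone demethylases known to escape X inactivation, were higher in XX than in XY. Kdm5c measured 334 ± 16.7 against 244 ± 13.2 CPM (SD, n = 5 each), a log2 difference of 0.45 ± 0.061 (SE, adjusted p = 0.000299). Kdm6a measured 109 ± 15.9 against 69.1 ± 9.83 CPM, a log2 difference of 0.66 ± 0.11 (adjusted p = 0.0053). In all, 12 of 15686 tested genes passed the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, 8 higher and 4 lower in XX. Beside these 2 demethylases, the higher ones were Xist, its antisense partner Tsix and 4 transcripts annotated inside or across the Xist gene, Gm26992, Gm27520, Gm27927 and Gm27733, which were named after their values were seen. Gm27927 and Gm27733 lie on the same strand as Xist, so strand would not part their reads from those of Xist. Reads of Tsix, Gm26992 and Gm27520, on the other strand, cannot be told from those of Xist without strand information where they overlap it. The 4 lower genes were Kdm5d, Eif2s3y, Ddx3y and Uty. At an unadjusted p below 0.05 there were 297 genes (1.89% of those tested), under the share of 0.05 that chance alone gives on average. In the 13 libraries with low B cell markers, which keep XY replicate 1 as the only XY library, neither Kdm5c nor Kdm6a passed in females (adjusted p = 1 for each), while their log2 differences were 0.43 and 0.74.

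Among gonadal males the picture was nearly the same, with 15 genes, 10 higher and 5 lower in XXSry than in XYSry. Kdm5c stood at 311 ± 16.1 against 228 ± 14.1 CPM (log2 difference 0.45 ± 0.061, adjusted p = 0.000337), and Kdm6a at 113 ± 13.5 against 72.2 ± 7.78 CPM (0.64 ± 0.11, adjusted p = 0.00717). Pbdc1, a gene near the Xist locus that is reported to escape X inactivation, was higher at 32.2 ± 7.87 against 19.4 ± 2.81 CPM (log2 difference 0.73 ± 0.14, adjusted p = 0.044), as was the pseudogene Gm2223 (adjusted p = 0.0199), which was named after its values were seen. The Pbdc1 call was lost in 16 of the 20 fits that left out 1 library, with adjusted p from 0.0515 without XX replicate 3 to 0.237 without XYSry replicate 1; it held only without XX replicate 1, XXSry replicate 1, XXSry replicate 2 and XYSry replicate 5. The autosomal gene in the set was Mgmt, a DNA repair methyltransferase on chromosome 7 (136894614 to 137130266), at 0.826 ± 0.151 CPM in XXSry and 1.94 ± 0.407 CPM in XYSry, or 12 to 46 counts per library. Its log2 difference of −1.23 ± 0.21 had an adjusted p of 0.00717 and missed the threshold in the 13 libraries with low B cell markers (log2 difference −1.24, adjusted p = 0.121) and without the library of each group richest in mitochondrial transcripts (−1.13, adjusted p = 0.106). The difference between the gonad types in this Mgmt effect was 1.11 ± 0.30 on the log2 scale and did not pass (adjusted p = 0.99). Of all genes tested, 443 (2.82%) had an unadjusted p below 0.05, again under the share of 0.05 that chance alone gives on average.

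Averaged over gonad types, XX cells carried more of a small set of X-linked transcripts than XY cells. Kdm5c (ENSMUSG00000025332, chromosome X, 152233020 to 152274535) was 1.37-fold higher at 323 ± 19.6 against 236 ± 15.4 CPM (SD, n = 10 each; adjusted p = 8.19e-07). Kdm6a (ENSMUSG00000037369, chromosome X, 18162575 to 18279936) was 1.57-fold higher at 111 ± 14.1 against 70.7 ± 8.52 CPM (adjusted p = 3.08e-05). Eif2s3x, a translation initiation factor subunit (chromosome X, 94188707 to 94212862), reached 19.7 ± 2.6 against 14.3 ± 1.33 CPM (adjusted p = 0.00643), and Pbdc1 (chromosome X, 105079756 to 105117090) reached 28.8 ± 7.03 against 19.3 ± 2.21 CPM (adjusted p = 0.0125). Xist itself stood at 1044 ± 249 against 2.94 ± 1.35 CPM.

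The averaged contrast called 16 genes, 12 higher and 4 lower in the XX complement. Beside these 4 protein-coding genes the higher ones were Xist, Tsix and the 4 transcripts overlapping Xist, together with Gm2223 (log2 difference 0.53 ± 0.077, adjusted p = 0.000873) and AC149090.1 on the unplaced scaffold JH584304.1 (0.83 ± 0.16, adjusted p = 0.0423), both named after their values were seen. AC149090.1 lost its call in 15 of the 20 fits that left out 1 library, at adjusted p from 0.0509 without XY replicate 1 to 0.127 without XYSry replicate 5; it was kept only without XX replicate 5, XY replicate 3, XY replicate 4, XXSry replicate 3 and XYSry replicate 2. With the replicate number as a block its adjusted p was 0.0545. Pbdc1 and AC149090.1 were also lost without the library of each group richest in mitochondrial transcripts (adjusted p = 0.317 and 0.056), at log2 differences of 0.55 and 0.79. In the 13 libraries with low B cell markers, Eif2s3x, Pbdc1, Gm2223 and AC149090.1 did not pass, at log2 differences of 0.45, 0.66, 0.64 and 0.73. The X-linked partner Ddx3x differed by 0.07 ± 0.084, and the inactivation-centre RNAs Ftx and Jpx by 0.35 ± 0.10 and 0.31 ± 0.13 on the log2 scale, none passing. 5530601H04Rik, next to Pbdc1, differed by 0.37 ± 0.079 (adjusted p = 0.112) and passed with DESeq2 (0.00575) and without XX replicate 4 (0.0443).

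**Figure D2:**
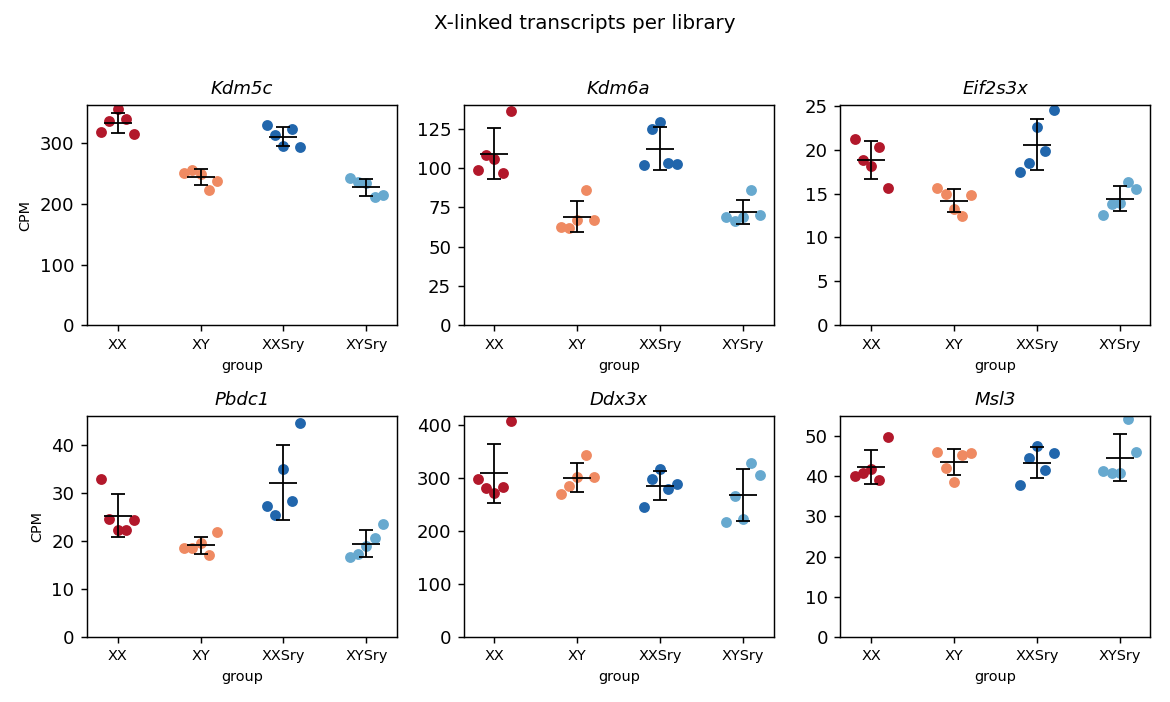
CPM of Kdm5c, Kdm6a, Eif2s3x, Pbdc1, Ddx3x and Msl3 per library in the groups XX, XY, XXSry and XYSry; points are libraries, bars the mean and SD of 5. Kdm5c means are 334 and 311 CPM with XX chromosomes and 244 and 228 CPM with XY chromosomes, while Ddx3x and Msl3 did not pass the test.

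As a class, X-linked genes were level with autosomal genes. The median log2 difference between complements was 0.0036 over 561 X-linked genes other than Xist and 0.0025 over 14834 autosomal genes (camera p = 0.060; p = 0.355 with an estimated correlation). Under a stricter filter on low counts the camera p was 0.036. Without the tested genes within 50 kb of Xist it was 0.37 over 554 genes, and without these and the escape and distal X lists 0.80 over 537 genes. The called genes were concentrated on the sex chromosomes, with 11 of 562 tested X-linked genes (Fisher's exact test, two-sided, adjusted p = 8.8e-12) and 4 of 6 Y-linked genes (adjusted p = 1.1e-10). Genes of the distal X segment, a region next to the pseudoautosomal boundary, did not differ (6 tested, 0 passed, camera adjusted p = 0.78, median below and mean above 0). Among them Msl3 differed by −0.04 on the log2 scale (95% CI −0.18 to 0.09), and Tlr7, an RNA sensor, by 0.13 (95% CI −0.44 to 0.71).

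Among the gene lists fixed in advance, the complement contrast moved the genotype lists most firmly. Of 12 tested genes of the X inactivation escape list 5 were higher in XX, or 9 when adjusted over the list alone (camera adjusted p = 1.06e-42; adjusted p = 1.05e-07 with an estimated correlation). This list holds Xist, which follows from the karyotype, and its mean log2 difference was 0.98 against a median of 0.36. Of 5 tested Y-linked genes 4 were lower, also when adjusted over the list alone (camera adjusted p = 4.04e-84; 1.10e-08 with an estimated correlation). The Y-linked result likewise follows from the karyotype. In the list of X-linked immune genes, 1 of 27 members passed, Kdm6a, also when adjusted over the list alone (camera adjusted p = 0.32). With 0 members passing by edgeR, 10 further lists had a camera adjusted p below 0.05. NK cell markers (0.000208), interferon response (0.00031), Th1 (0.0047), ribosomal proteins (0.0060), dendritic cell markers (0.0075), CD8 T cell markers (0.0149) and glycolysis (0.0177) leaned towards XX. Th17 (0.000459), cholesterol synthesis (0.000768) and apoptosis and p53 (0.0047) leaned towards XY. With an estimated correlation the adjusted p of these 10 lists was 0.127 to 0.660. Only NK cell markers, Th17 and apoptosis and p53 kept the preset call whichever library was left out. In the 13 libraries with low B cell markers the calls of Th17 (adjusted p = 0.532) and apoptosis and p53 (0.246) were lost too, as were those of ribosomal proteins (0.119), cholesterol synthesis (0.899) and glycolysis (0.981, direction turned). On leaving out 1 library, the others lost it without XX replicates 1, 3 or 4, XY replicates 1, 2 or 4, XXSry replicates 1, 2 or 5, or XYSry replicates 2 or 4, at adjusted p from 0.0564 to 0.769.

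Within gonadal females 7 lists passed camera and within gonadal males 15, and only the escape and Y-linked lists passed in either with an estimated correlation. In females 3 members of the escape list were higher (7 adjusted over the list alone) and in males 4 (8 adjusted over the list alone), Xist among them in both. Cytokines and chemokines (0.000187), cell cycle (5.49e-05), nuclear oxidative phosphorylation (0.000539) and cholesterol synthesis (0.0089) leaned towards XY in females. B cell markers had a mean log2 CPM of 3.17 ± 2.18 in XX and 3.90 ± 1.21 in XY (SD, n = 5 each), with XX replicate 4 at 6.58. Their female test pointed down (0.0015, and 1.2e-21 without XX replicate 4). The median and mean of their fitted log2 differences were 0.46 and 0.45, above 0. The adjusted p of these 5 lists was 0.996 with an estimated correlation, and each lost its preset call on leaving out 1 library. Cytokines and chemokines (0.109) and oxidative phosphorylation (0.440) lost it without XX replicate 5, and cell cycle without XX replicate 3 (0.162). Cholesterol synthesis lost it without XX replicate 3, XX replicate 5, XY replicate 2 or XY replicate 5 (0.0867 to 0.231). B cell markers lost it without XX replicates 1, 2 or 3 or XY replicates 3 or 5 (0.0702 to 0.307). In males, of the lists other than these 2, interferon response leaned towards XXSry with the smallest camera adjusted p (3.07e-10) and 0 members passing by edgeR. With an estimated correlation the 13 further male lists had an adjusted p of 0.32 to 0.861, and 12 of them lost the preset call without XY replicate 2, XXSry replicates 1, 2, 3 or 5, or XYSry replicates 2, 3, 4 or 5 (adjusted p = 0.0508 to 0.917).

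Gonad type separated the libraries far more widely than the complement did. Whether gonadal males were immunized is not stated, so this contrast may also hold a difference in immunization. Of the gene lists, 21 of 23 cholesterol synthesis, 8 of 10 inhibitory receptor, 10 of 15 Th17 and 20 of 39 cytokine and chemokine members were lower in gonadal females than in gonadal males. By contrast, 7 of 17 naive and memory, 16 of 58 ribosomal protein and 7 of 21 glycolysis members were higher. These lists passed camera with the preset correlation, and none passed with an estimated one (lowest adjusted p = 0.097 with an estimated correlation). Granzyme C (Gzmc, chromosome 14, 56231441 to 56234656), a cytotoxic serine protease, was 5.2-fold lower at 14.3 ± 3.8 against 75.4 ± 22.3 CPM (SD, n = 10 each; log2 difference −2.38 ± 0.14, adjusted p = 4.75e-10). The cytokine GM-CSF (Csf2, chromosome 11, 54247271 to 54249667) was 3.65-fold lower at 10.1 ± 3.78 against 36.2 ± 6.21 CPM (−1.87 ± 0.16, adjusted p = 4.58e-08), and Dapl1 (chromosome 2, 59484653 to 59505020), a transcript of naive T cells, was 4.83-fold higher at 3.28 ± 0.826 against 0.684 ± 0.32 CPM (2.27 ± 0.21, adjusted p = 9.21e-08). By the edgeR quasi-likelihood test 3873 of 15686 genes (24.7%) passed, 1787 higher and 2086 lower in gonadal females, with a median absolute log2 difference of 0.37. More than 2-fold differences were found for 106 higher and 447 lower genes. Values of the 10 female and 10 male libraries did not overlap for 415 of the 15686 tested genes (2.65%; chance gives 0.00108%). In the 13 libraries with low B cell markers, of which 4 came from gonadal females, 1202 genes passed, 1115 of them among the 3873.

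The lower genes with the smallest p came from several functions. Kit, the stem cell factor receptor (chromosome 5, 75574916 to 75656722), was 2.95-fold lower at 17.0 ± 2.77 against 50.3 ± 8.11 CPM (adjusted p = 5.75e-10). The mast cell proteases Cma1 and Tpsb2 were lower at 0.678 ± 0.323 against 4.97 ± 1.01 CPM and 2.16 ± 0.72 against 15.4 ± 3.76 CPM. Podnl1 stood at 57.4 ± 6.65 against 124 ± 11.8 CPM, and Srgap3, the titin gene Ttn and the matrix protein gene Npnt were 3.66-, 3.58- and 4.64-fold lower, with adjusted p from 4.97e-10 to 1.16e-08. Among the higher genes, the protease-activated receptor F2rl1 was 2.55-fold higher at 22.5 ± 2.85 against 8.81 ± 1.7 CPM, and the chemokine receptor Cxcr2 was higher at 23.7 ± 3.52 against 8.05 ± 2.67 CPM. Clstn3 and the RNA-binding protein gene Khdrbs3 were 3.47- and 6.03-fold higher, Izumo1r, a folate receptor of regulatory T cells, 1.61-fold, and Las1l, an X-linked gene of ribosome assembly, 1.39-fold. All of these higher genes had an adjusted p between 1.66e-08 and 9.39e-08.

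Genes of the Th17, Th2 and Th1 lists were among those lower in gonadal females. Of 15 tested Th17 genes 10 were lower and 0 higher, the same when adjusted over the list alone (camera adjusted p = 5.1e-07; adjusted p = 0.097 with an estimated correlation). Rora, a nuclear receptor active in Th17 cells, stood at 138 ± 13.8 CPM in gonadal females and was 1.55-fold higher in gonadal males (SD, n = 10; adjusted p = 1.41e-06). Il17a, named after its values were seen, was lower at 123 ± 48.6 against 212 ± 60.6 CPM (log2 difference −0.78, adjusted p = 0.0102). Its call was lost in the libraries with low B cell markers (−0.64, adjusted p = 0.248) and without the library of each group richest in mitochondrial transcripts (−0.73, adjusted p = 0.0538). Il17f did not pass (adjusted p = 0.197), except without XX replicate 1 (0.0119). Of 13 Th2 genes 8 were lower and 1 higher (8 and 2 adjusted over the list alone; camera adjusted p = 0.00087; adjusted p = 0.33 with an estimated correlation), among them the growth factor Areg (3.11-fold), the IL-33 receptor Il1rl1 (1.78-fold) and Il13 at 16.6 ± 7.1 against 58.4 ± 21.3 CPM (adjusted p = 3.22e-05). Of 15 Th1 genes 7 were lower and 1 higher (8 and 1 adjusted over the list alone; camera adjusted p = 0.0126; adjusted p = 0.42 with an estimated correlation). Interferon gamma (Ifng, chromosome 10, 118441046 to 118445892) was 2.26-fold lower at 126 ± 33.6 against 286 ± 72.8 CPM, and the granule protein gene Nkg7 2.68-fold lower. Of 39 cytokines and chemokines 20 were lower and 3 higher (22 and 4 adjusted over the list alone; camera adjusted p = 4.5e-06; adjusted p = 0.40 with an estimated correlation), with the chemokine Xcl1 at 2.06 ± 0.674 against 10.5 ± 6.63 CPM.

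**Figure D3:**
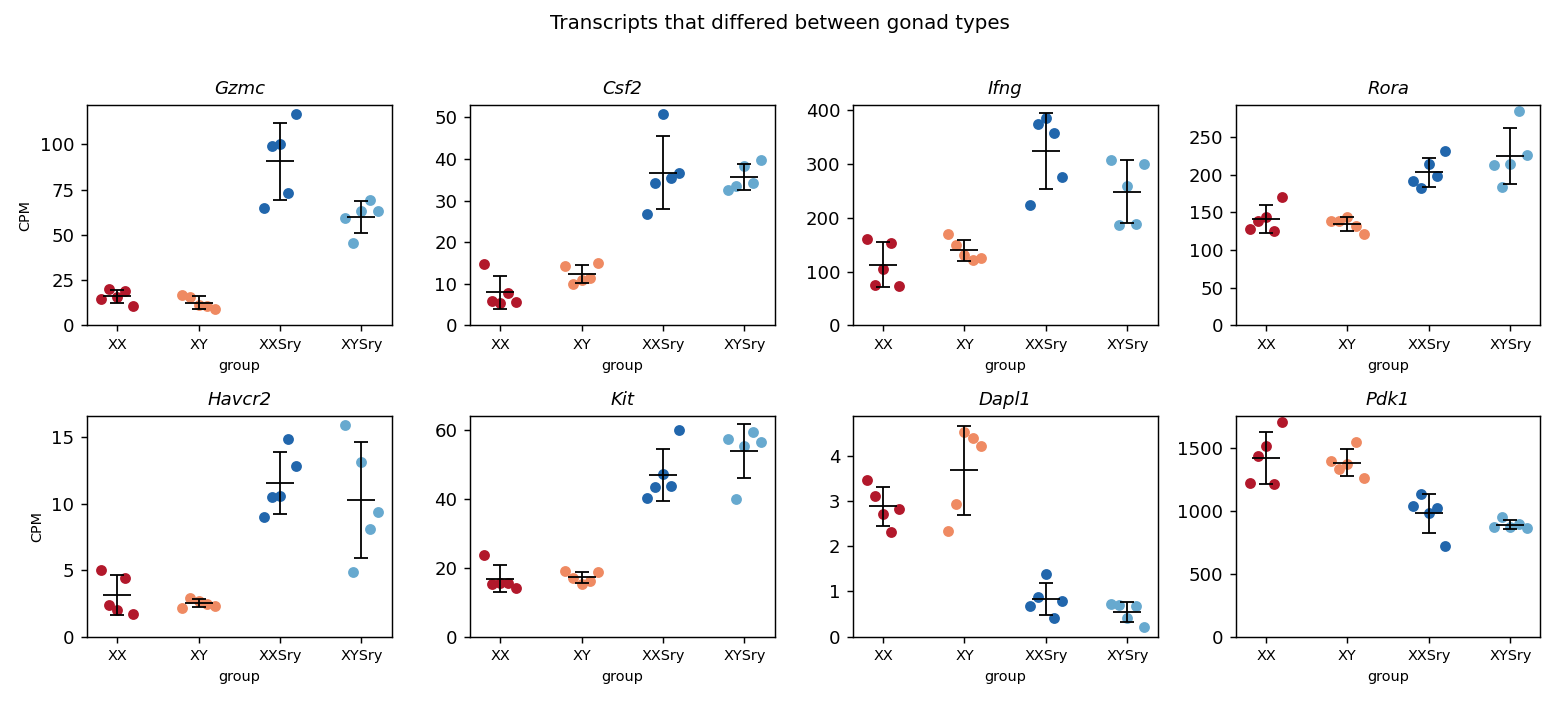
CPM of Gzmc, Csf2, Ifng, Rora, Havcr2, Kit, Dapl1 and Pdk1 per library in the groups XX, XY, XXSry and XYSry; points are libraries, bars the mean and SD of 5. Gzmc averages 14.3 CPM over the gonadal females and 75.4 CPM over the gonadal males, and Dapl1 3.28 and 0.684 CPM.

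Most inhibitory receptor genes were lower in gonadal females, as were some genes of T cell receptor signalling. Of 10 inhibitory receptor genes 8 were lower and 0 higher (9 and 0 adjusted over the list alone; camera adjusted p = 1.1e-06; adjusted p = 0.097 with an estimated correlation). Havcr2, which encodes TIM-3, stood at 2.81 ± 1.07 against 10.9 ± 3.35 CPM, Pdcd1, which encodes PD-1, at 50.7 ± 9.51 against 114 ± 29.1 CPM, and Cd160 at 2.06 ± 0.357 against 4.94 ± 1.32 CPM (adjusted p = 6.79e-07, 2.64e-06 and 1e-06). Of 24 T cell receptor activation genes 9 were lower and 1 higher (11 and 1 adjusted over the list alone; camera adjusted p = 0.00033; adjusted p = 0.45 with an estimated correlation), such as the NF-kappaB inhibitor Nfkbia (1.42-fold lower) and the adhesion receptor Cd44 (1.70-fold lower). Naive and memory markers went the other way, with 7 of 17 higher and 1 lower (8 and 1 adjusted over the list alone; camera adjusted p = 0.00082; adjusted p = 0.42 with an estimated correlation). The egress receptor S1pr1 rose from 512 ± 78.8 in gonadal males to 683 ± 69.2 CPM in gonadal females and the chromatin organizer Satb1 from 1081 ± 92.5 to 1279 ± 75.7 CPM, while the survival gene Bcl2 was the lower one (1.24-fold, adjusted p = 0.00123), a call lost in the libraries with low B cell markers (log2 difference −0.24 against −0.31, adjusted p = 0.151). Of 12 follicular helper genes 3 were lower and 0 higher (3 and 1 adjusted over the list alone; camera adjusted p = 0.106), among them Pdcd1 and Tox2 (22.4 ± 3.47 against 45.3 ± 14.2 CPM). Regulatory T cell genes were split, with 8 of 19 lower and 3 higher (10 and 4 adjusted over the list alone; camera adjusted p = 0.208), the higher ones including Izumo1r and Gpr83 (1.74-fold, adjusted p = 2.05e-05).

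Among metabolic and growth genes, cholesterol synthesis was the list with most members lower in gonadal females. All but 2 of the 23 cholesterol synthesis genes passed as lower (21 lower, 0 higher; 23 and 0 adjusted over the list alone; camera adjusted p = 7.8e-10; adjusted p = 0.36 with an estimated correlation). The sterol-regulated gene Insig1 stood at 50.7 ± 5.78 against 70.1 ± 6.99 CPM (adjusted p = 3.82e-05). Of 37 cell cycle genes 10 were lower and 0 higher (12 and 0 adjusted over the list alone; camera adjusted p = 0.00022; adjusted p = 0.57 with an estimated correlation). The proliferation marker Mki67 was 1.42-fold and the kinetochore gene Cenpf 1.45-fold lower (adjusted p = 0.00945 and 0.00953), or log2 differences of −0.51 and −0.53. Both calls were lost without the library of each group richest in mitochondrial transcripts (−0.44 and −0.47, adjusted p = 0.0846 and 0.0665) and in the libraries with low B cell markers (−0.59 and −0.71, adjusted p = 0.124 and 0.076). Of 58 ribosomal protein genes 16 were higher and 0 lower (17 and 0 adjusted over the list alone; camera adjusted p = 4.5e-06; adjusted p = 0.36 with an estimated correlation), with Rpl12 1.35-fold higher (adjusted p = 0.000201). Of 21 glycolysis genes 7 were higher and 2 lower (8 and 2 adjusted over the list alone; camera adjusted p = 0.0288; adjusted p = 0.47 with an estimated correlation). The pyruvate dehydrogenase kinase Pdk1 stood at 1400 ± 157 against 936 ± 117 CPM (adjusted p = 5.62e-06) and the glucose transporter Slc2a3 at 1217 ± 190 against 908 ± 107 CPM (adjusted p = 0.000813). The glycolysis call was lost without XX replicate 3 (0.0513), XXSry replicate 2 (0.0537) or XYSry replicate 2 (0.0589).

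**Figure D4:**
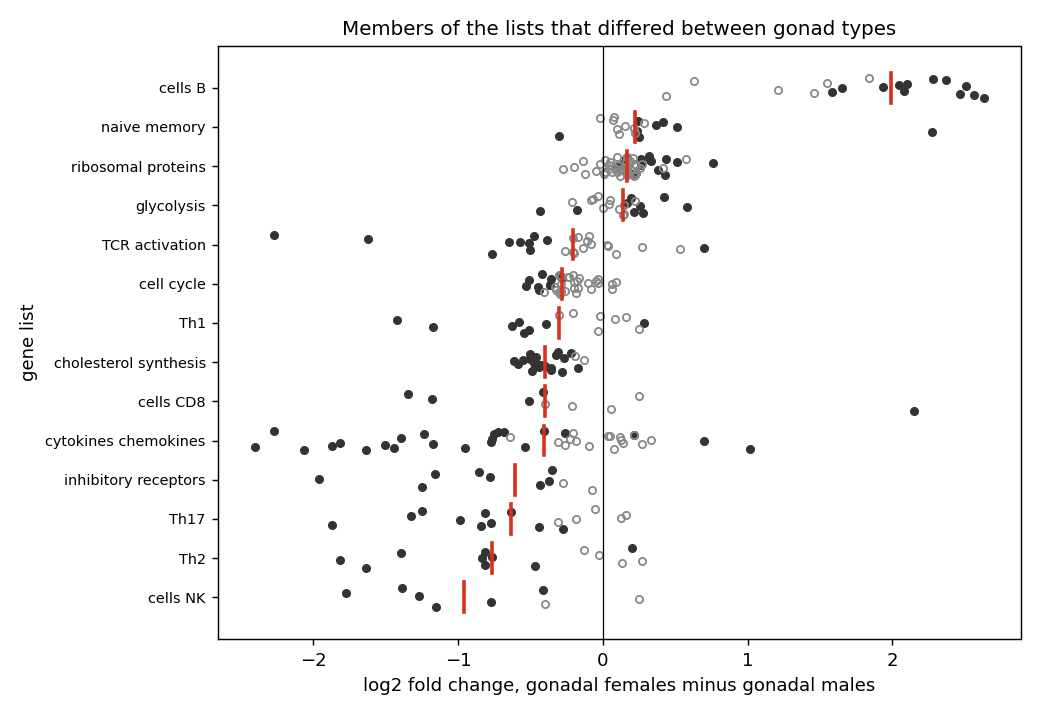
Log2 difference of gonadal females minus gonadal males for each tested member of the 14 gene lists that passed camera with the preset correlation; filled points passed the test over all genes, open points did not, and the red bar is the list median. Medians lie below 0 for the T helper, inhibitory receptor and cholesterol lists (for example −0.63 for Th17 and −0.40 for cholesterol synthesis) and above 0 for ribosomal proteins (0.17) and naive and memory markers (0.22).

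Markers of other cell types moved with the gonad type beside these groups. Of 18 B cell markers 12 were higher in gonadal females and 0 lower (17 and 0 adjusted over the list alone; camera adjusted p = 0.0015; adjusted p = 0.57 with an estimated correlation). Their mean log2 CPM was 3.53 ± 1.71 in gonadal females and 2.38 ± 0.763 in gonadal males (SD, n = 10 each), and it exceeded 3 in XX replicates 4 and 5, XY replicates 2 to 5 and XXSry replicate 1. Cd22, a B cell receptor inhibitor, stood at 63.3 ± 92.8 against 11.8 ± 13.4 CPM (log2 difference 2.47, adjusted p = 0.0271). Cd22 did not pass without XX replicate 4, where the difference was 1.36 (adjusted p = 0.0768), with the replicate number as a block (2.15, adjusted p = 0.124) or without the library of each group richest in mitochondrial transcripts (2.38, adjusted p = 0.11), and in the libraries with low B cell markers it was −0.16 (adjusted p = 0.782). NK cell markers were lower in gonadal females, 6 of 8 with 0 higher, the same adjusted over the list alone (camera adjusted p = 2.1e-05; adjusted p = 0.097 with an estimated correlation), at a mean log2 CPM of 1.43 ± 0.207 against 2.26 ± 0.275. Ncr1, an NK cell receptor, stood at 1.89 ± 0.403 against 6.55 ± 2.56 CPM. Of 9 CD8 T cell markers 4 were lower, among them Klrk1 (2.54-fold), and 1 higher, the same adjusted over the list alone (camera adjusted p = 0.0288; adjusted p = 0.42 with an estimated correlation), a call lost without XY replicate 1 (0.0619) or XXSry replicate 2 (0.0537). Plasma cell markers had 1 higher member of 8 (0 adjusted over the list alone; camera adjusted p = 0.957). Macrophage markers had 3 higher and 4 lower of 12, the same adjusted over the list alone, with a median and mean above 0 and a test pointing down (camera adjusted p = 0.799). Dendritic cell markers had 2 higher and 4 lower of 10 (2 and 5 adjusted over the list alone), with a median of −0.13, a mean of 0.047 and a test pointing down (camera adjusted p = 0.160). Stromal markers had 1 higher and 1 lower of 5, the same adjusted over the list alone (camera adjusted p = 0.588). Only 3 neutrophil and 3 erythroid markers were tested, too few for a set test, with 1 higher and 1 lower (2 and 1 adjusted over the list alone) and 0 passing (0 adjusted over the list alone).

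The remaining lists did not pass camera in the gonad contrast. Interferon response genes were balanced, with 5 higher and 5 lower of 42 (6 and 6 adjusted over the list alone; adjusted p = 0.735). Nuclear oxidative phosphorylation had 1 higher and 2 lower of 52 (0 and 1 adjusted over the list alone; adjusted p = 0.195), and the 7 mitochondrially encoded transcripts tested had 0 passing (0 adjusted over the list alone; adjusted p = 0.289). X-linked immune genes had 4 higher and 1 lower of 27 (1 and 0 adjusted over the list alone; adjusted p = 0.141), and apoptosis and p53 genes 2 higher and 5 lower of 19 (3 and 6 adjusted over the list alone; adjusted p = 0.141). Glucocorticoid and steroid response genes had 3 higher and 4 lower of 14 (4 and 6 adjusted over the list alone; adjusted p = 0.763), with a median above 0, a mean below 0 and a test pointing down. Heat shock and stress genes had 6 higher and 2 lower of 20 (7 and 3 adjusted over the list alone; adjusted p = 0.218). Histone demethylase and polycomb genes had 1 lower of 17 (0 adjusted over the list alone; adjusted p = 0.112), distal X genes 3 lower of 6 (3 adjusted over the list alone; adjusted p = 0.160), and the escape list 1 higher and 1 lower of 12, the same adjusted over the list alone (adjusted p = 0.764). T cell identity genes had 1 higher and 1 lower of 12, the same adjusted over the list alone (adjusted p = 0.588). In the Y-linked list only Sry passed, also when adjusted over the list alone (adjusted p = 0.289 for the 5 genes). None of the 32 lists tested passed in the gonad contrast with an estimated correlation, while 18 passed fry. Cell cycle (fry adjusted p = 0.069) and B cell markers (fry adjusted p = 0.128), both called by camera, did not pass fry. By chromosome, 100 of 562 X-linked genes changed with gonad type (17.8%, odds ratio 0.651, Fisher's exact test, two-sided, adjusted p = 0.0017), and no chromosome passed under the stricter filter on low counts.

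The gonad effect recurred in each complement. Taken alone, XX differed from XXSry in 1401 genes (625 higher, 776 lower) and XY from XYSry in 1831 genes (631 higher, 1200 lower), contrasts added after the data were seen that share no libraries. Of these, 899 genes passed in both and all 899 had the same direction, 299 higher and 600 lower. Independent lists would share 25.1 and 59.4. Both contrasts take the spread of each gene from the same fit, so the lists are not independent and these expected numbers are only a rough guide. Across 14834 autosomal genes, which are not independent replicates, the log2 differences of the gonad contrast in XX and in XY had a Pearson correlation of 0.774, whereas those of the complement contrast in females and in males had one of −0.058. The gonad differences had the same sign in both complements for 72.5% of these autosomal genes. For the complement differences in females and in males this share was 38.6%.

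No gene showed a complement effect that differed between gonad types. Kdm5c and Kdm6a differed between XX and XY by nearly the same amount in both, with interaction estimates of 0.0031 ± 0.085 and 0.022 ± 0.15 on the log2 scale. The edgeR interaction test called 0 of 15686 genes, with 555 (3.54%) at an unadjusted p below 0.05 and a smallest adjusted p of 0.99. DESeq2 also called 0, with 603 at an unadjusted p below 0.05 and a smallest adjusted p of 0.27. Both counts are under the share of 0.05 that chance alone gives on average. On simulated data of this depth, 34.3% of genes with a 1.5-fold interaction, 61.2% at 2-fold and 90.9% at 3-fold were recovered. Small interactions would therefore often be missed. These genes had a mean above 1 CPM, and recovery of weaker genes was not simulated. Of the lists, interferon response (camera adjusted p = 3.3e-07), cell cycle (4.2e-05), nuclear oxidative phosphorylation (9.4e-05), cytokines and chemokines (0.000115), B cell markers (0.000418) and ribosomal proteins (0.0461) had a complement effect that was lower in females, with 0 members passing by edgeR and an adjusted p = 0.79 with an estimated correlation for each.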

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

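The tests on B cell markers, batch labels, Sry reads, XY replicate 5 and mast cell genes were chosen only after the results were seen, whereas the regroupings of libraries were fixed before the data were examined. A library was taken to stand apart when its gap to the nearest of its group of 5 exceeded 0.71 of the range (Dixon's test). For independent normal values this happens by chance in about 5 percent of groups. It held for 40 of 387 groups, or 10.3%. Gene values were CPM without logs and the groups reuse the same libraries, so the 5 percent is no firm reference here. List values below are mean log2 CPM and gene values CPM.

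XX replicate 1 stood apart in the Th2 list (4.59), the Th17 list (6.01), Pbdc1 (32.98), Kit (23.5), Csf2 (14.8) and Il13 (27.2). XX replicate 4 stood apart in dendritic cell markers (4.51), Mgmt (1.36), F2rl1 (16.3) and Cd22 (314). XX replicate 5 stood apart in Xist (1227), Ddx3x (407), Ftx (32.8), Msl3 (49.9) and Izumo1r (136). Among XY libraries, replicate 1 stood apart in Satb1 (1381), replicate 3 in Npnt (3.78), replicate 4 in Kdm6a (86.1) and Nfkbia (231), and replicate 5 in Kdm5d (129). XXSry replicate 1 stood apart in Cd22 (49.2), and XXSry replicate 5 in the nuclear oxidative phosphorylation list (5.82) and Pdcd1 (177). XYSry replicate 2 stood apart in the inhibitory receptor list (4.62), the cholesterol synthesis list (5.58), Mgmt (2.64), AC149090.1 (36.6), Sry (121) and Kit (39.9). XYSry replicate 3 stood apart in Jpx (2.52). XYSry replicate 4 stood apart in the nuclear oxidative phosphorylation list (5.44), the ribosomal protein list (4.63), Xist (6.58), Kdm6a (86.0), Ddx3y (109), Uty (47.9), Npnt (39.6) and Rpl12 (40.7), and XYSry replicate 5 in Ttn (46.8) and Cd160 (6.63).

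In the interaction contrast, lists passed camera with the preset correlation although 0 genes passed: interferon response (adjusted p = 3.3e-07), cell cycle (4.2e-05), nuclear oxidative phosphorylation (9.4e-05), cytokines and chemokines (0.000115), B cell markers (0.000418) and ribosomal proteins (0.0461). With an estimated correlation the adjusted p was 0.79 for each. The call was lost for cell cycle (0.0652) and oxidative phosphorylation (0.0592) without XXSry replicate 5, and for B cell markers without XX replicate 1 (0.0751) or XXSry replicate 1 (0.0505). Ribosomal proteins kept it only without XX replicates 3 or 4, XY replicates 2 or 4, XXSry replicate 3 or XYSry replicates 1, 2 or 3, and reached 0.618 without XYSry replicate 4; with the replicate number as a block their adjusted p was 0.0556.

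The breadth of the gonad contrast could come from B cells left in some libraries, from a batch, or from the Sry transgene acting in the T cells apart from the gonads. A difference in immunization could also contribute, as the series text describes it for female mice only. The labels do not settle this, so immunization cannot be told apart from gonad type. With the B cell marker mean as a covariate, 79.7% of the calls lower in gonadal females (1663 of 2086) and 70.2% of the higher ones (1255 of 1787) were kept, which goes against B cells as the whole cause. Among calls above 2-fold, 429 of 447 lower but only 45 of 106 higher ones were kept, so B cells may account for many of the large increases. NK cell markers were lower in gonadal females (6 of 8), and no fit took them into account. Whether NK cells carry part of the lower Th1, cytokine or inhibitory receptor genes was not tested. The labels name 0 batches, so a culture or sequencing batch that coincides with gonad type cannot be told apart from gonad type. In 0 libraries do Sry reads and gonad type part, so transgene and gonads cannot be told apart either.

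XY replicate 5 carried more Y-linked transcript than the other 4 XY libraries, with ratios of 1.99 for Kdm5d, 1.85 for Eif2s3y, 1.73 for Ddx3y and 1.69 for Uty. The summed Kdm5c, Eif2s3x and Ddx3x CPM had a ratio of 0.992 (554 against 559) while the Y partners gained 218, which goes against reads moved from the X-linked partners. Uty also reached 46.0 CPM in another XY library. What raised these transcripts stays open.

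Mast cell protease transcripts were higher in gonadal males, and mast cells in those libraries may be the source, although the CD4+ sorting or negative selection that the labels describe would remove most of them. Over the 10 Sry libraries with group means removed, Tpsab1, Tpsb2, Mcpt4, Cma1 and Cpa3 had a median pairwise r of 0.873 (range 0.203 to 0.991 over 10 pairs, permutation p = 0.0001). This r was not recomputed without the 2 libraries farthest in Tpsab1, XXSry replicate 5 (23.7 CPM) and XYSry replicate 5 (18.0 CPM). They may therefore carry part of it. Against mast cells as the source, Cpa3 (2.35 CPM), Fcer1a (0.351) and Ms4a2 (0.0897) stayed far below Tpsab1 (36.7) in gonadal males, although mast cells are rich in them. For Kit the relation to Tpsab1 was r = −0.28 (95% CI −0.77 to 0.43, permutation p = 0.427), Spearman rho = 0.0061 (permutation p = 1), and r = 0.46 without the 2 farthest libraries. The rule for this Kit test was revised after its value was seen, from counting against mast cells to leaving it open, so whether mast cells carry the Kit difference cannot be told apart from expression by T cells.

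Chance was tested with 100 groupings of the libraries per contrast, the true one included. For gonad type only 1 of the 100, the true one, gave as many calls, the highest other giving 70 against 3873. None of the other groupings drawn came near the true count. The test takes each library as a separate unit, which the labels do not state. It therefore cannot exclude chance between animals or cultures. For XX and XY gonadal females 1 of the 100 did (highest other 10 against 12). For the complement contrast 3 of the 100 did (highest other 997 against 16). Most of the true calls in both were Xist-locus or Y-linked genes, which follow from the karyotype itself. Mixing XX with XY libraries removes such calls, so these counts cannot decide on chance. For XXSry and XYSry gonadal males 7 of the 100 gave as many (highest other 744 against 15), so chance cannot be excluded for the count, which says nothing of the 14 calls on the sex chromosomes, where Xist alone had an adjusted p of 3.2e-15. In the interaction all 100 gave at least 0 calls, the highest other 288. Groupings that call this many genes point to a structure of the samples: the 744 came from setting XXSry replicates 3 and 5 with XYSry replicates 1, 4 and 5.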

How the results depend on the processing

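The B cell and mitochondrial alternatives were chosen only after the data were seen. The counts of changed genes held under RLE size factors (gonad contrast 3949), no low-count filter (3685), the strict filter (3614) and DESeq2 (4348). Leaving out 1 library gave 3284 (without XXSry replicate 5) to 4478 (without XX replicate 1), and the interaction stayed at 0. Fits of only the 2 groups compared called 10 genes in females (6 higher, 4 lower). In males such fits called 12 (8 higher, 4 lower), against 10 higher and 5 lower in the main fit. With the B cell covariate 3127 genes were called, without the library of each group richest in mitochondrial transcripts 2673, and in the 13 libraries with low B cell markers 1202. These 13 keep 1 XY library, which is assumed to vary like the other groups. The list results depended most on the test and on the correlation taken between genes. With an estimated correlation the number of lists passing camera fell from 7 to 2 in females and from 15 to 2 in males. It fell from 12 to 2 for the complement, from 14 to 0 for the gonad contrast and from 6 to 0 for the interaction. Fry, which does not set a list against other genes, passed 2 lists in females, 2 in males and 2 for the complement. It passed 18 for the gonad contrast and 0 for the interaction. Under the strict filter the X-linked set in the complement contrast had a camera value of 0.036 and the chromosomes in the gonad contrast went from 1 to 0. With the B cell covariate, B cell markers in females turned direction (adjusted p = 0.936). The covariate is the mean of these same markers, so the loss of their call was set in advance. In the libraries with low B cell markers, 2 lists passed in females and 3 in the interaction. There the direction turned for cell cycle (adjusted p = 0.868) and cholesterol synthesis (0.981) in females, glycolysis in the complement contrast (0.981), B cell markers in the gonad contrast (0.00952) and Cd22 (log2 difference −0.16). Without the libraries richest in mitochondrial transcripts 3 lists passed in the interaction. Leaving out 1 library gave 4 (without XX replicate 5) to 8 lists (without XX replicate 1) in females and 4 (without XX replicate 1) to 10 (without XX replicate 4) in the interaction. In males, cell cycle ranged from an adjusted p of 7.7e-05 (without XXSry replicate 2) to 0.535 (without XYSry replicate 2), turning direction without XXSry replicate 5 (0.332), and oxidative phosphorylation from 0.000961 (without XXSry replicate 2) to 0.917 with the direction turned (without XXSry replicate 5). Tlr7 in the complement contrast ranged from −0.0043 (without XX replicate 4) to 0.26 (without XY replicate 4). The cause of these changes was not tested. Depth limits what can be seen of weak transcripts such as Mgmt. Alternatives for normalized values were not run, as the table holds counts.

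The replicate number as a block left 11 genes in females, 14 in males, 15 for the complement and 3608 for gonad type, and ended the call of ribosomal proteins in the interaction (adjusted p = 0.0556). Of 30 pairs of libraries with the same number, 10 had a residual correlation above 0.1 and 14 below −0.1 (−0.43 to 0.37, median −0.051), and 3 of 20 libraries correlated best with their own number, so the numbers were not taken as pairs.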

Other observations

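Foxp3, Gata3 and Tbx21, regulators of T cell lineages, did not pass in the gonad contrast and were picked after their values were seen. Whether they differ less than effector genes was not tested, and Tbx21 had the lower mean in gonadal females, as most called Th1 genes did. Foxp3 (197 ± 32.7 against 192 ± 23.8 CPM), Gata3 (122 ± 9.49 against 112 ± 10.6 CPM), Tbx21 (43.9 ± 14.9 against 54.4 ± 8.46 CPM) and Cd4 (985 against 1068 CPM) did not pass in gonadal females against gonadal males (SD, n = 10 each). Cd8a, the higher member of the CD8 T cell markers, was 4.43-fold higher in gonadal females by the fit, at 2.14 ± 2.08 against 0.48 ± 0.11 CPM (log2 difference 2.15 ± 0.51, edgeR adjusted p = 0.00448), against the direction of that list. Among libraries with XX chromosomes, Xist stood at 745.8 to 1227 CPM in XX and 1071 to 1490 CPM in XXSry, and Tsix at 82.5 ± 5.25 and 132 ± 12.0 CPM (SD, n = 5 each), chosen after the values were seen. In the contrast of XX with XXSry over all genes, Tsix passed (log2 difference −0.68 ± 0.11, edgeR adjusted p = 0.000517) and Xist did not (−0.47 ± 0.19, adjusted p = 0.117). The 2 differences were not tested against each other, and without the strand setting Tsix reads cannot be told from Xist reads.

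The libraries richest in mitochondrially encoded transcripts were XX replicate 5 (10.5 mean log2 CPM), XY replicate 4 (10.4), XXSry replicate 3 (10.6) and XYSry replicate 4 (11.2), the others reaching at most 10.1. After group means were removed, the 6 pairs among these 4 libraries had correlations of 0.319 to 0.508 (median 0.38), against a median of −0.021 over the 144 other pairs across groups (highest 0.419). This comparison was chosen only after the values were seen.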
